A study of Mus musculus with 22 samples.

How the data were processed

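RNA abundance was measured in mouse liver on Affymetrix 3-prime expression arrays, 1 array per liver sample and 22 arrays in all. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns and turned into biotin-labelled cRNA. The deposited values are log2 expression summaries, 1 per probe set, that the authors had already normalized between arrays; the submitters' processing notes name the affy package. The background correction, the normalization and the summary method are not given in the sources used here. The log2 scale was read from the values, which ran from 1.73 to 13.5 with 0 missing. The array medians lay between 5.64 and 5.71.

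The table held 12488 probe sets, among them 66 control probe sets that were left out. Through the platform's probe table, 10833 probe sets carried 1 gene symbol, 396 carried several and 1193 carried none. Probe sets with several symbols or none were named after no gene and stayed out of the tests of genes. Symbols were checked against the RefSeq gene table of assembly GRCm38.p6 through their gene identifiers, and 0 needed updating. One probe set stood for a gene, that with the highest mean log2 value over all arrays, which left 8251 genes; 2073 of them had more than 1 probe set. No pair of arrays held identical values, and the closest pair had a Pearson r of 0.997 across genes. Precision is limited by the number of arrays, and the text gives it as standard errors.

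The design has 1 array per genotype and condition, and the labels do not say whether a liver sample came from 1 mouse or from a pool. In the tests by phase, livers taken at different times therefore stood in for replicates. Their p-values measure only the spread between these arrays, which includes true change between times. In the response at each time the 2 genotypes stood in for replicates. The spread there is shared by all times, and a genotype difference that varies between conditions, as at 4 h, enlarges it. Arrays were grouped by genotype and phase. Controls were the untreated, PBS 4 h and PBS 12 h arrays, early times were 0.5, 1, 2 and 4 h, and late times were 12, 16, 24 and 48 h. Each condition occurred in both genotypes, and these 2 arrays were treated as a pair that shares treatment and time.

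All gene tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over the 8251 genes and a threshold of 0.05. The response at each time was the mean of both genotypes at that time minus the mean of the 6 control arrays, in an additive model of condition and genotype over 22 arrays with 10 residual degrees of freedom. Early and late responses within a genotype came from a model of 6 groups (genotype by phase) with 16 residual degrees of freedom. Genotype differences were fitted on the 11 within-pair differences, SOCS1-/-IFNg-/- minus IFNg-/-, as the mean of the 3 phase means (called over all pairs), in controls, and as the early or late difference minus that in controls (8 residual degrees of freedom). The difference of a single pair from the other 10 pairs was fitted with 9 residual degrees of freedom.

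Lists of genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Of 777 genes on 23 pathway lists and 14 cell type lists, 550 were measured. Camera with an estimated correlation and fry were the alternatives. Camera tests a list against the other genes, and fry tests it against no change. Members past the threshold were counted over all genes and adjusted over the list alone. A set of 91 induced genes was taken from both genotypes together. These passed limma's moderated F test over the 8 times at 0.05, and their largest time coefficient was at least 1 on the log2 scale and larger in size than any fall. Their mean log2 value per array gave a score, whose within-pair differences were tested by exact two-sided permutations and sign flips (4 tests in that family).

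The comparisons, the lists, the phases, the score, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names Socs1 and Ifng first, up to 12 genes higher and 8 lower per comparison by size among those past the threshold (the 5 largest rises at each time), and up to 4 members of each list described. Time courses are given for Socs1, Irf1, Cxcl9, Cxcl10, Gbp2, Igtp, Ciita, Socs3 and Cish, which were fixed in advance. The list tests at each time, the comparison of the 4 h pair with the other pairs, the phases redrawn, the counts without both PBS 12 h arrays and the score of the 4 to 24 h pairs were added after the data were seen. Members of lists named because they passed the threshold at a time, and Nr1d1, were chosen after their values were seen.

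Each fit was tested on simulated data for 8251 genes, of which 67 were changed by 0.5 and 67 by 1. At a log2 change of 1, limma recovered 98.5% in the 4 h response, 98.5% in the early response, 98.5% in the late genotype difference, 100% in the genotype difference over all pairs and 94.0% in the 4 h pair. At a log2 change of 0.5 the recovered shares were 86.6%, 88.1%, 64.2%, 98.5% and 20.9%. Among 100 simulated late genotype differences camera called a list of 20 genes shifted by 0.5 in 100, and an unshifted list in 4. The simulated change was the same on every changed array, and genes were drawn independently of each other. The recovered shares therefore do not hold for responses that differ between the times of a phase. Nor does the camera result hold for lists of correlated genes.

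The alternatives fixed in advance were median centring, quantile normalization, leaving out the genes with the lowest means, all probe sets, eBayes with robust fitting and a trend over mean expression (also where pair differences were fitted), array weights, PBS arrays only as controls, each genotype fitted alone, no pairing, and leaving out each array or pair in turn. Tables were prepared with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.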

Results

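The series followed the liver response to interferon-gamma in mice that lack the cytokine and in mice that lack both the cytokine and SOCS1, the suppressor of cytokine signalling that binds JAK kinases and is itself induced by interferon-gamma. Mice lacking interferon-gamma (IFNg-/-) and mice lacking both (SOCS1-/-IFNg-/-) were injected intraperitoneally with 4 µg of recombinant interferon-gamma in 100 µl, so that the cytokine reached the liver as a single dose. Livers were taken 0.5, 1, 2, 4, 12, 16, 24 and 48 h later. Controls were an untreated liver and livers taken 4 and 12 h after 100 µl of PBS. Each genotype had 11 arrays, 3 control, 4 early (0.5 to 4 h) and 4 late (12 to 48 h), with 1 array for each condition and no replicates. Values are log2 expression, and differences are log2 differences with the standard error (SE) of the fit.

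Both deleted genes were examined first. Socs1 stayed between 6.57 and 7.02 on the 11 SOCS1-/-IFNg-/- arrays. On the IFNg-/- arrays it was 6.73 untreated, 7.37 at 1 h, 9.21 at 2 h and 6.89 at 4 h, and between 6.68 and 6.80 from 12 h on. Ifng lay between 2.18 and 2.61 on all 22 arrays, near the lowest value on an array of 1.73. The part of either gene that its probes cover was not compared with the deletions.

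Genes were called from 1 h on, and limma called the most at 4 h, a ranking that array weights turned round. PBS livers were taken at 4 and 12 h alone. At 0.5, 1, 2, 16, 24 and 48 h, which have no PBS liver of the same time, the design therefore does not separate interferon-gamma from injection or handling. At 4 and 12 h the response was set against all control arrays, untreated ones included. The counts there do not separate them either. In both genotypes together, limma called 0 genes at 0.5 h (smallest adjusted p 0.369; 478 at an unadjusted p under 0.05, where chance gives 413), 13 at 1 h, 137 at 2 h, 415 at 4 h, 117 at 12 h, 37 at 16 h, 14 at 24 h and 1 at 48 h. With array weights the counts were 420 at 2 h and 84 at 4 h. Rises made up all 13 genes at 1 h, 102 at 2 h, 259 at 4 h and 108 at 12 h. Of the 91 induced genes, 32 were highest at 2 h, 32 at 4 h and 18 at 12 h. Adjusted over these 91 alone, which were chosen on the same arrays and so are not independent evidence, 1, 37, 82, 90, 48, 35, 16 and 1 passed at the 8 times. 

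**Figure D1:**
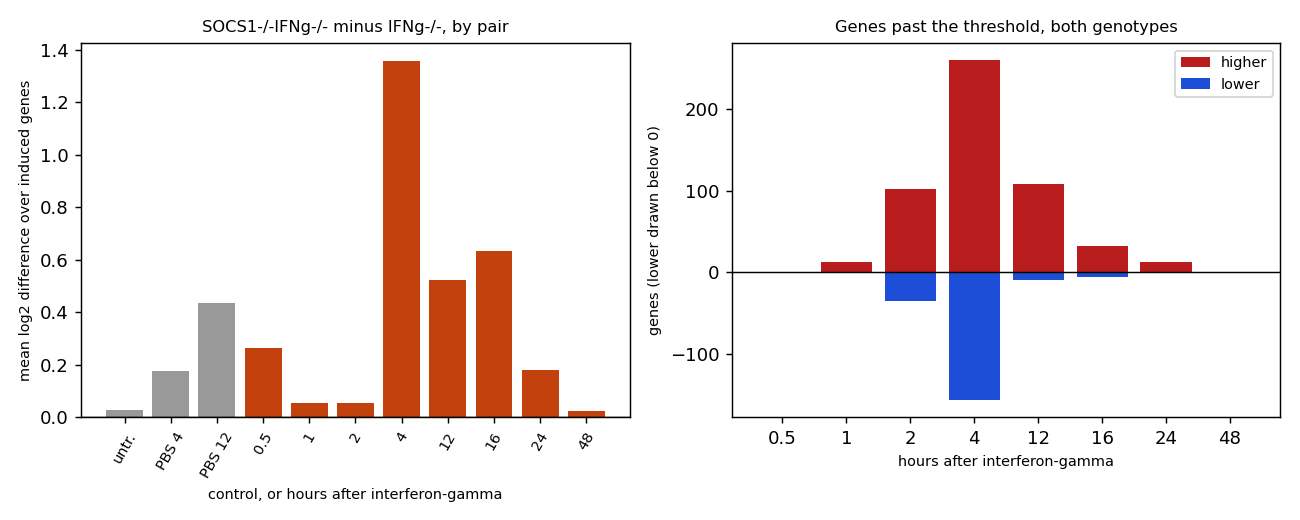
Left, mean log2 difference (SOCS1-/-IFNg-/- minus IFNg-/-) over the 91 induced genes in each pair, controls in grey and interferon times in orange, 1 array per genotype; the 4 h pair stands at 1.36. Right, number of genes past the limma threshold at each time in both genotypes together, those higher drawn upward and those lower drawn below 0, with 259 higher and 156 lower at 4 h.

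At 1 h the largest rises among the genes called were in Irf1, a transcription factor directly induced by interferon-gamma (2.89 ± 0.42 SE, adjusted p = 0.00776), and Egr1, an immediate early transcription factor (2.71 ± 0.44). Next were Gdap10 (2.17 ± 0.34), the immunity-related GTPase Irgm1 (1.87 ± 0.33) and the monocyte chemokine Ccl2 (1.87 ± 0.31). Cxcl9 differed by 1.93 ± 0.49 and was not called (adjusted p = 0.26), with raised PBS 12 h arrays among its controls. Above the untreated and PBS 4 h arrays it stood 3.32 in IFNg-/- and 3.03 in SOCS1-/-IFNg-/-. Of the 9 measured GTPases induced by interferon-gamma, Irgm1, Irgm2 and Iigp1 rose (3; adjusted over the list alone, 6). As a list the GTPases shifted up at 1 h by camera (adjusted p = 2.72e-16), but adjusted p = 0.114 with an estimated correlation. The other probe set of Egr1, with a lower mean, gave -0.20. Of the genes named, Irgm1 lost its call in 2 of 10 fits that left out a pair, and Egr1, Gdap10, Ccl2 and Iigp1 in 1. Without both untreated arrays the count at 1 h was 7, and without the 4 h pair it was 47. With trend and robust fitting it was 6, and with array weights 43.

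At 2 h chemokine, GTPase, antiviral and metallothionein genes were among the largest rises. Cxcl9 rose by 4.54 ± 0.49 (adjusted p = 0.000171) and Cxcl10 by 4.43 ± 0.71; both encode ligands of the T cell receptor CXCR3. Gbp2, a guanylate-binding protein, rose by 4.25 ± 0.62, the antiviral enzyme Rsad2 by 3.87 ± 0.71 and the metal-binding Mt2 by 3.87 ± 0.54. The raised PBS 12 h arrays are among these controls. Against the untreated and PBS 4 h arrays alone Cxcl9 stood 5.9 higher in IFNg-/- and 5.6 in SOCS1-/-IFNg-/-, and Gbp2 5.3 and 4.9. Of 9 GTPases 8 rose (adjusted over the list alone, 8), of 23 chemokines 5 (5), of 23 immediate early genes 10 (14) and of 26 acute phase proteins 5 (13). Of 14 feedback inhibitors of cytokine signalling 3 rose (6), Socs2 by 2.99 and Socs3 by 1.58, and of 20 JAK-STAT genes 3 (6), Irf1 by 3.43. Of 23 cell death genes 2 rose (7) and of 14 glucocorticoid targets 3 (7). Some genes stand on more than 1 list, as Mt1, Mt2 and Lcn2 do on the acute phase and glucocorticoid lists. Camera called each of these lists, also with an estimated correlation (adjusted p from 0.0286 for GTPases to 0.0476 for chemokines). Of 23 antiviral genes shared with type I interferon, 8 rose (15), with adjusted p = 6.34e-22 by camera and adjusted p = 0.0534 with an estimated correlation. Mid1ip1, which promotes fatty acid synthesis, changed by -1.75 ± 0.36 and Nr0b2, the nuclear receptor SHP that represses bile acid synthesis, by -0.87 ± 0.17 (lost in 1 of 10 fits that left out a pair). Cholesterol synthesis genes had a median of -0.31, and 0 of 17 passed (0 adjusted over the list alone; adjusted p = 0.654 with an estimated correlation). Without both untreated arrays 86 genes were called at 2 h, without the 4 h pair 287, and without both PBS 12 h arrays 109.

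At 4 h more acute phase genes were called than at 2 h, and some metabolic genes fell. Gbp2 rose by 4.32 ± 0.62 (adjusted p = 0.000994), Cxcl9 by 4.14 ± 0.49, Mt2 by 4.04 ± 0.54, Mt1 by 3.86 ± 0.58 and the GTPase Ifi47 by 3.69 ± 0.27. With only the untreated and PBS 4 h arrays as controls, Gbp2 stood 3.5 higher in IFNg-/- and 6.9 in SOCS1-/-IFNg-/-, and Cxcl9 3.75 and 7.02. Of 26 acute phase proteins, 15 rose (adjusted over the list alone, 20), among them Lcn2, an iron-binding lipocalin (2.90), and the serum amyloid gene Saa2 (2.71), and 8 of 9 GTPases rose (8). Adjusted p was 0.0199 and 0.0246 with an estimated correlation. On the PBS 4 h arrays 19 of these 26 acute phase genes stood above untreated in both genotypes, and the list's median shift was 0.29. In the cell death list 8 of 23 rose (10), with Daxx at 1.30, the death receptor Fas at 1.25 and Casp8 at 0.89 (calls lost in 3 of 10 fits that left out a pair for Daxx and in 1 for Casp8). In the JAK-STAT list 7 of 20 rose (8). Both were called with an estimated correlation (adjusted p = 0.0254 and 0.0199). Of 23 antiviral genes 15 rose (18; adjusted p = 0.0918 with an estimated correlation) and of 18 MHC class I genes 4 rose (8; adjusted p = 0.071 with an estimated correlation), the peptide transporter Tap1 by 2.05. The 4 h values are means of arrays that differ: Mx1 stood at 3.63 in IFNg-/- and 9.33 in SOCS1-/-IFNg-/-. The SOCS1-/-IFNg-/- 4 h array had the lowest median correlation with other arrays (0.979). Its 3-prime to 5-prime Actb difference was also the lowest (0.33), which is not a mark of degraded RNA.

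Some genes of glucose production and lipid synthesis fell at 4 h against all control arrays together. They were not tested against the PBS 4 h arrays alone. G6pc, the last enzyme of glucose release, changed by -2.24 ± 0.39 (adjusted p = 0.00388). Cavin2 changed by -1.33 ± 0.23, Ddc by -1.17 ± 0.10, the lipogenic factor Srebf1 by -1.14 ± 0.22, the acyltransferase Gpam by -1.08 ± 0.23 and the amino acid enzyme Tat by -1.04 ± 0.16. Of 19 genes of fasting metabolism 4 fell and 1 rose (5 and 1 adjusted over the list alone), of 16 fatty acid synthesis genes 3 fell (5) and of 17 cholesterol synthesis genes 2 fell (5), Lss by -0.75 and Mvd by -0.57. Each list was called by camera (adjusted p = 0.0276, 0.00464 and 0.000398), but adjusted p = 0.439 with an estimated correlation in all 3. Of 13 bile acid genes 2 fell (5; adjusted p = 0.195 with an estimated correlation), among them Cyp8b1, by -0.71. The clock repressor Nr1d1 stood at 7.41 and 7.21 on the 4 h interferon arrays and at 7.58 and 7.57 on the PBS 4 h arrays, against 5.68 and 6.48 untreated (IFNg-/- first). Gpam, Lss and Cyp8b1 lost their calls in 1 of 10 fits that left out a pair. Without both untreated arrays the 4 h count was 228, and without both PBS 12 h arrays it was 262, with 249 genes shared with the full fit.

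At 12 h Cxcl9, GTPases and acute phase genes were among the largest rises. Cxcl9 rose by 5.68 ± 0.49 (adjusted p = 2.31e-05), Gbp2 by 4.66 ± 0.62, Lcn2 by 3.97 ± 0.42, Saa2 by 3.16 ± 0.42 and Gm9706 by 2.99 ± 0.63. Leaving the raised PBS 12 h arrays out of the controls, Cxcl9 stood 6.7 higher in IFNg-/- and 7.2 in SOCS1-/-IFNg-/-, and Gbp2 4.6 and 6.5. The other probe set of Lcn2, with a lower mean, gave 0.22 at 12 h (0.08 at 4 h). Of 18 MHC class I genes 9 rose (adjusted over the list alone, 12), the immunoproteasome subunits Psmb8 by 1.83, Psmb9 by 1.59 and Psmb10 by 1.28. Of 26 acute phase proteins 13 rose (19) and Hamp, the iron hormone hepcidin, changed by -2.37 ± 0.44. Of 9 GTPases 8 rose (9) and of 20 JAK-STAT genes 4 (8). These 4 lists had adjusted p = 0.0164 with an estimated correlation. Of 14 MHC class II genes 3 rose (5; adjusted p = 0.105 with an estimated correlation), the invariant chain Cd74 by 1.26, and of 23 antiviral genes 3 rose (8; adjusted p = 0.236 with an estimated correlation). Of 23 genes of fatty acid oxidation 3 fell (6; adjusted p = 0.145 with an estimated correlation), Acaa1b by -0.87, Acot1 by -0.64 and Slc25a20 by -0.39. Gm9706 and Acaa1b lost their calls in 2 of 10 fits that left out a pair. Without both untreated arrays 54 genes were called at 12 h, without the 4 h pair 187 and without both PBS 12 h arrays 132.

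At 16 and 24 h fewer genes were called. At 16 h Cxcl9 rose by 5.42 ± 0.49 (adjusted p = 5.55e-05), Lcn2 by 4.26 ± 0.42, Gbp2 by 4.11 ± 0.62, Saa2 by 3.29 ± 0.42 and Saa3 by 2.95 ± 0.51. Of 26 acute phase proteins 10 rose (adjusted over the list alone, 17), of 18 MHC class I genes 3 (10) and of 14 MHC class II genes 1 (7). These were called also with an estimated correlation (adjusted p = 0.0206, 0.0287 and 0.0287). Of 9 GTPases 2 rose (7; adjusted p = 0.109 with an estimated correlation). The other probe set of Lcn2 gave 0.10 at 16 h and 0.11 at 24 h. The carboxylesterase Ces1d changed by -1.27 ± 0.22 at 16 h. At 24 h Lcn2 rose by 4.50 ± 0.42 (adjusted p = 0.00014), Cxcl9 by 4.31 ± 0.49, Saa2 by 3.35 ± 0.42, Saa3 by 2.91 ± 0.51 and Serpina3n by 1.51 ± 0.17. Relative to the untreated and PBS 4 h arrays alone, Cxcl9 stood 6.2 and 7.1 higher at 16 h and 5.1 and 6.0 at 24 h (IFNg-/- first). The call of Saa3 was lost in 6 of 10 fits that left out a pair at 24 h and in 1 at 16 h. Of 26 acute phase proteins 5 rose at 24 h (11), with adjusted p = 0.317 with an estimated correlation. The gene called at 48 h was Abcc3, a transporter of bile acids and conjugates, 0.80 ± 0.11 higher (adjusted p = 0.0264), and the call was lost in 4 of 10 fits that left out a pair. Without both untreated arrays 15 genes were called at 16 h and 9 at 24 h, and without the 4 h pair 60 and 22. At 24 h 7 were called without the PBS 4 h pair, without the 0.5 h pair 8, without the 2 h pair 9 and without the 16 h pair 22.

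The time courses of the genes fixed in advance are given for each genotype without a test, since each point is 1 array. Irf1 was 9.83 at 1 h and 10.56 at 2 h in IFNg-/- and 10.06 and 10.38 in SOCS1-/-IFNg-/-; at 4 h it was 7.71 against 10.73, and at 12 h 7.72 against 7.64. Cxcl10 was 8.53 at 2 h and 4.54 at 4 h in IFNg-/-, and 7.89 and 9.42 in SOCS1-/-IFNg-/-. Cxcl9 went from 4.16 untreated to 10.25 at 2 h, 8.06 at 4 h, 10.99 at 12 h and 5.54 at 48 h in IFNg-/-, and from 4.31 to 9.93, 11.33, 11.48 and 5.13 in SOCS1-/-IFNg-/-. Gbp2 at 2, 4, 12, 16 and 24 h was 9.73, 7.89, 8.96, 8.08 and 5.44 in IFNg-/- and 9.36, 11.34, 10.94, 10.73 and 7.64 in SOCS1-/-IFNg-/-. Igtp at 4 and 12 h was 8.61 and 8.03 against 10.50 and 9.54. At 2 h the median genotype difference of the GTPases was -0.20, with 3 of 9 higher in SOCS1-/-IFNg-/-. Socs3 was 7.76 at 2 h and 7.35 at 4 h in IFNg-/-, and 8.18 and 8.44 in SOCS1-/-IFNg-/-. Ciita, the master regulator of MHC class II genes, stayed between 5.71 and 6.13 on all arrays, and Cish, a further SOCS family member, between 6.15 and 7.30.

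**Figure D2:**
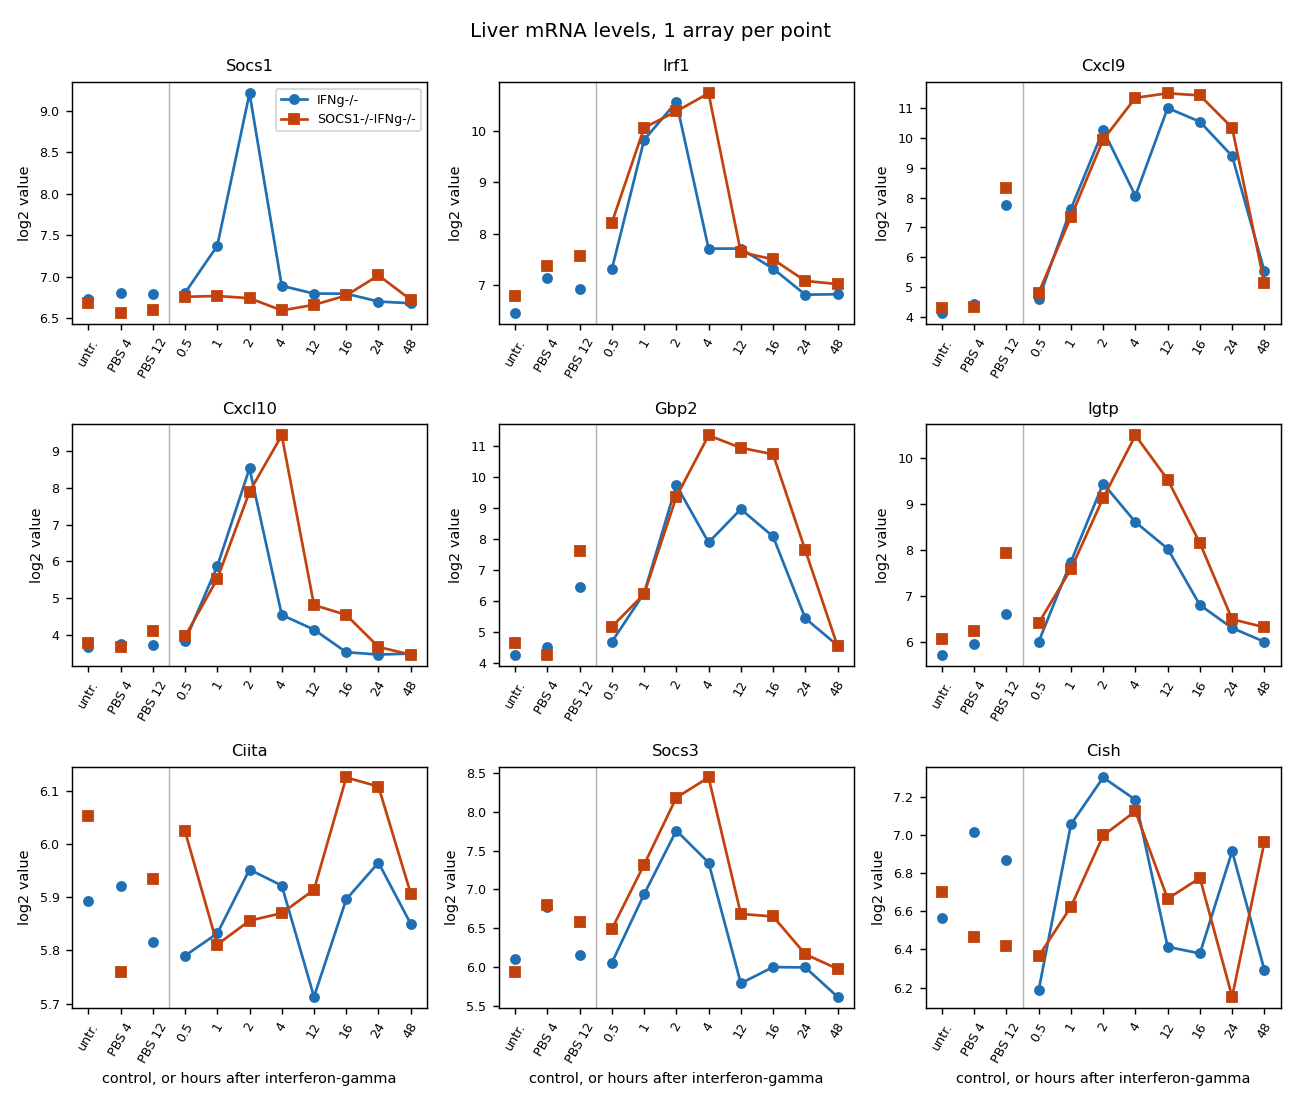
Log2 values of 9 genes in IFNg-/- (blue circles) and SOCS1-/-IFNg-/- (orange squares) livers, 1 array per point; the 3 controls stand left of the grey line and the hours after interferon-gamma, at unequal spacing, right of it, and each panel has its own axis. Cxcl10 at 4 h was 4.54 in IFNg-/- and 9.42 in SOCS1-/-IFNg-/-, and Socs1 reached 9.21 in IFNg-/-.

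For the vehicle injection limma called 2 genes (51 with array weights), and the PBS 12 h arrays carried interferon-inducible transcripts. Against untreated livers, PBS (4 arrays against 2) raised Id2, an inhibitor of basic helix-loop-helix factors, by 1.22 ± 0.15 (adjusted p = 0.00673). It changed the replication gene Mcm10 by -1.12 ± 0.16 (adjusted p = 0.0233, not called without the PBS 12 h pair). In all, 966 genes had an unadjusted p under 0.05, where chance gives 413. RNA quality moved with this contrast: the 3-prime to 5-prime Actb difference was 1.32 and 1.31 on the untreated arrays and 0.66 to 0.83 on the PBS arrays. That of Gapdh was 0.85 and 0.66 against 0.37 to 0.55. Both PBS 12 h arrays were higher in Cxcl9 (7.76 and 8.31, against 4.46 and 4.33 at PBS 4 h) and Gbp2 (6.44 and 7.60, against 4.53 and 4.27). The median of the 9 GTPases there lay 0.71 (IFNg-/-) and 1.28 (SOCS1-/-IFNg-/-) above the untreated and PBS 4 h arrays of the genotype. These arrays are among the controls of every time and phase, and without them PBS called 1 gene; without the PBS 4 h pair it called 9, without the 4 h interferon pair 14 and without the 48 h pair 4.

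**Figure D3:**
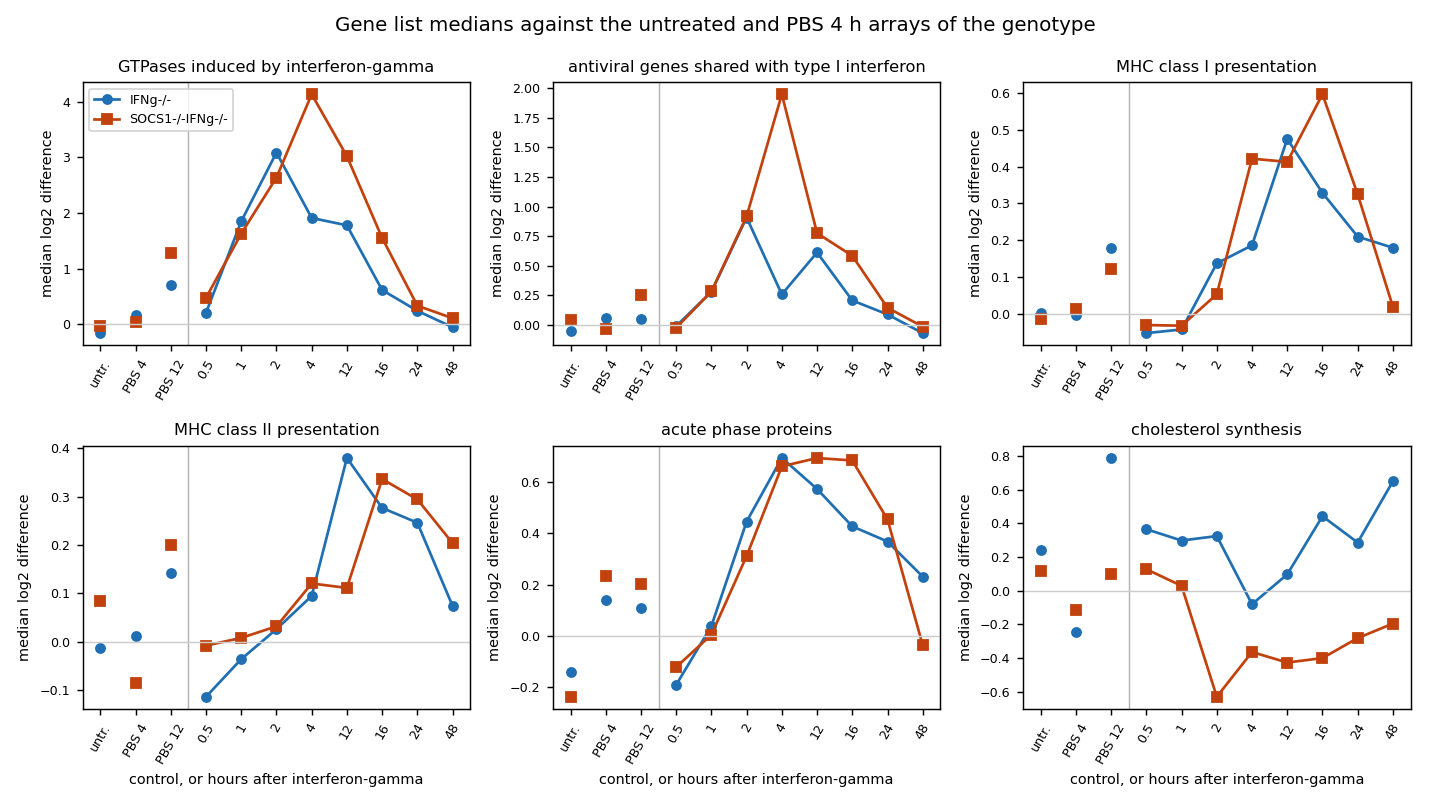
Median log2 difference of the measured members of 6 gene lists on each array against the mean of the untreated and PBS 4 h arrays of the same genotype (IFNg-/- blue circles, SOCS1-/-IFNg-/- orange squares), controls left of the grey line and hours after interferon-gamma right of it, each panel on its own axis. The GTPases stand at 0.71 and 1.28 on the PBS 12 h arrays.

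Within a genotype, the early and late phases against controls gave few calls. In IFNg-/- limma called 0 genes early (232 at an unadjusted p under 0.05) and 0 late (370). In SOCS1-/-IFNg-/- it called Egr1 early, 2.96 ± 0.44 higher (adjusted p = 0.0126; 548 at an unadjusted p under 0.05), and 0 late (775). The Egr1 call was lost without the PBS 4 h, the 1 h or the 2 h array of that genotype; without the untreated array 5 genes were called early and without the 0.5 h array 8. Without its 48 h array the late count in SOCS1-/-IFNg-/- was 66 (20 higher), without its 16 h array 8 and without its untreated array 4, and in IFNg-/- 1 gene was called early without the 4 h array. With array weights 4 genes were called early and 6 late in SOCS1-/-IFNg-/-, and 55 late with redrawn phases, a setting chosen after the data were seen. Camera called 10 lists early and 5 late in IFNg-/-, and 12 early and 12 late in SOCS1-/-IFNg-/-. One of these kept its call with an estimated correlation, complement in the late IFNg-/- response (adjusted p = 0.022), where 14 of 20 members were above controls and 0 passed over all genes (adjusted over the list alone, 1). GTPases had early medians of 1.64 in IFNg-/- and 1.66 in SOCS1-/-IFNg-/- (adjusted p = 0.421 and 0.379 with an estimated correlation), and Lcn2 had late differences of 3.26 and 3.25, neither past the threshold (adjusted p = 0.948 and 0.362).

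Across all 11 pairs, loss of SOCS1 went with higher MHC class II transcripts. Cd74, the invariant chain, was 0.91 ± 0.08 higher in SOCS1-/-IFNg-/- (adjusted p = 0.000381; 11 of 11 pairs), H2-Aa 0.64 ± 0.08 higher (11 of 11) and H2-Ab1 0.36 ± 0.05 higher (11 of 11). The monocyte gene Plac8 was 0.70 ± 0.10 higher (11 of 11), the pentraxin Apcs 0.63 ± 0.12 (11 of 11). Igkv6-23 was 0.59 ± 0.10 higher, Postn 0.31 ± 0.05, Ly6e 0.30 ± 0.04, Alyref 0.25 ± 0.04 and Clec16a, the neighbour of Socs1 among the measured genes on GRCm38.p6, 0.22 ± 0.03 (11 of 11). The protease gene Ctse differed by -1.12 ± 0.11 (adjusted p = 0.000416; lower in 11 of 11) and Csad, an enzyme of taurine synthesis, by -0.90 ± 0.16. The mitochondrial transhydrogenase Nnt differed by -0.83 ± 0.10 and Cyp4a12b by -0.51 ± 0.05 (lower in 11 of 11), with Mcm10, Arhgap5, Alas2 and Lactb2 between -0.35 and -0.26. Of the 18 genes called, Cd74, H2-Aa, H2-Ab1, Ctse, Nnt and Cyp4a12b kept their calls in each of 11 fits that left out a pair, while Apcs, Csad, Arhgap5 and Alas2 lost theirs in 9. Alyref lost its call in 8, Igkv6-23, Mcm10 and Lactb2 in 7, Postn in 6, Plac8 in 2, and Ly6e and Clec16a in 1. Of 2 further probe sets of Ctse, the weaker gave 0.07 and the stronger -1.10, and that of Ly6e gave -0.06. The count was 7 without the PBS 12 h pair, 8 without the 24 h pair, 10 without the untreated pair, 11 without the 0.5, 1 or 2 h pair and 31 without the 48 h pair. With trend and robust fitting it was 14, without pairing by treatment and time 4, with PBS arrays alone as controls 10 and with array weights 71 (43 higher).

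Among lists, 3 of 14 MHC class II genes were higher over all pairs (adjusted over the list alone, 7). The list was called by camera (adjusted p = 2.21e-13), also with an estimated correlation (adjusted p = 0.0349). By fry, which tests a list against no change and not against other genes, adjusted p was 0.00223. Without the PBS 12 h pair it had adjusted p = 0.0721 with an estimated correlation. Of the 9 GTPases 0 passed over all genes in limma and 9 adjusted over the list alone, Gbp2 at 1.00, Gbp3 at 0.72 and Igtp at 0.65 (camera adjusted p = 4.09e-11; adjusted p = 0.123 with an estimated correlation). Of 26 acute phase proteins Apcs was called (adjusted over the list alone, 11 higher and 1 lower), with Mt1 at 1.44 and Mt2 at 1.24 (adjusted p = 0.123 with an estimated correlation). Of 23 antiviral genes 0 were called (1), with Isg15 at 0.86 (adjusted p = 0.316 with an estimated correlation). Of 8 monocyte genes 1 was higher (2; adjusted p = 0.123 with an estimated correlation), and 13 of 13 bile acid genes were lower in SOCS1-/-IFNg-/- but 0 passed (3; adjusted p = 0.123 with an estimated correlation). Of the 91 induced genes 41 passed when adjusted over that list alone, 39 of them higher in SOCS1-/-IFNg-/-. In all, 710 genes had an unadjusted p under 0.05.

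In the 3 control pairs Ctse was the gene called (-1.63 ± 0.20, adjusted p = 0.0182; 373 at an unadjusted p under 0.05), and 0 genes were called without the PBS 12 h pair. Without the PBS 4 h pair Ctse was not called either and 1 other gene was. The count was 3 without the 12 h interferon pair and 2 without the untreated, 0.5 h or 24 h pair. limma called 0 genes with trend and robust fitting and 0 without pairing, which ends the Ctse call, and 27 with array weights. MHC class II genes had a median difference of 0.18 there (camera adjusted p = 1.4e-07; adjusted p = 0.204 with an estimated correlation), with 0 of 14 past the threshold over all genes and 5 adjusted over the list alone. Cd74 differed by 0.75 and H2-Aa by 0.55 in controls, neither past the threshold. In each list that follows limma called 0 members over all genes (adjusted over the list alone, 5 acute phase proteins and 0 in the others). Cholesterol synthesis genes had a median of 0.26 (camera adjusted p = 0.000222; adjusted p = 0.8 with an estimated correlation), with Hmgcs1 at 0.54 and Msmo1 at 0.46. Fatty acid synthesis genes had one of 0.15 (0.0139; adjusted p = 0.8 with an estimated correlation). Complement had 0.06 (0.0151; adjusted p = 0.488 with an estimated correlation) and Kupffer cell markers 0.09 (0.0379; adjusted p = 0.8 with an estimated correlation). The camera calls of these 4 lists were lost without the PBS 4 h pair. Heat shock genes had a median of -0.14 (0.0144; adjusted p = 0.8 with an estimated correlation), with Creld2 at -0.73, a call lost without the untreated pair. GTPases had one of 0.42 (0.000934; adjusted p = 0.8 with an estimated correlation), lost without the PBS 12 h pair. Acute phase proteins had one of 0.16 (5.06e-08; adjusted p = 0.472 with an estimated correlation), with Mt1 at 2.19.

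Whether loss of SOCS1 changed the response itself was tested as the genotype difference at early or late times minus that in controls. limma called 0 genes early (287 at an unadjusted p under 0.05) and 0 late (938), with a smallest late adjusted p of 0.0786. Without the untreated pair 2 genes were called late, and without the 4 h or the 24 h pair 1. With array weights 62 were called late, 54 of them lower. In the late phase, cholesterol synthesis genes had a median of -0.50 (2 of 17 above 0), which includes the opposite difference in controls, with Hmgcs1, an early enzyme of the pathway, at -1.13, Msmo1 at -1.08, Nsdhl at -0.98 and Idi1 at -0.75. Over all genes 0 passed, and 5 adjusted over the list alone (camera adjusted p = 5.99e-07; adjusted p = 0.452 with an estimated correlation). Drug-metabolising P450s had a median of -0.28 with Cyp2b10 at -1.11 (camera adjusted p = 5.74e-06; adjusted p = 0.0947 with an estimated correlation). Bile acid genes had one of -0.22 with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -1.95 (camera adjusted p = 0.000278; adjusted p = 0.317 with an estimated correlation). Early, antiviral genes had a median of 0.39, with Mx1 at 1.75 (camera adjusted p = 3.13e-05; adjusted p = 0.9 with an estimated correlation), a call lost without the 4 h pair. Camera called cell marker lists in the late difference too: hepatocyte markers had a median of -0.14 (camera adjusted p = 0.00219; adjusted p = 0.32 with an estimated correlation) and Kupffer cell markers one of -0.21. Monocyte markers had one of 0.17 and NK cell markers one of 0.14 (adjusted p = 0.49 with an estimated correlation for these 3). The clock transcript Nr1d1 differed within some pairs: it stood at 7.30 in IFNg-/- and 5.96 in SOCS1-/-IFNg-/- at 16 h, and at 5.68 and 6.48 untreated. Whether the pairs were matched in hour of day is not known from the labels and was not tested.

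The 4 h interferon pair differed from all other pairs in 277 genes, 227 of them higher in SOCS1-/-IFNg-/-. Antiviral effectors led: Mx1 by 5.39 ± 0.43 (adjusted p = 4e-06), Rsad2 by 4.81 ± 0.36, Ifit1 by 4.79 ± 0.32, Ifit2 by 4.28 ± 0.39 and Ifit3 by 4.22 ± 0.31. The nucleotide kinase Cmpk2 was higher by 4.21 ± 0.23, the nucleotide hydrolase Samhd1 by 3.94 ± 0.61 and Gm9706 by 3.89 ± 0.57. The ISG15 protease Usp18 was higher by 3.62 ± 0.23 and Isg15 by 3.48 ± 0.46, with the chemokines Cxcl10 by 4.74 ± 0.40 and Cxcl9 by 3.07 ± 0.42. Of 23 antiviral genes 17 were higher (adjusted over the list alone, 18; adjusted p = 0.00553 with an estimated correlation). Of 23 cell death genes 5 were higher (8), with Daxx at 2.26 and Casp8 at 1.25, and of 20 JAK-STAT genes 6 (6), with Irf1 at 2.74 and Irf8 at 2.17 (adjusted p = 0.0255 with an estimated correlation for both). Of 9 GTPases 3 were higher (5; adjusted p = 0.468 with an estimated correlation), and of 18 MHC class I genes 3 (6; adjusted p = 0.112 with an estimated correlation). Of 14 feedback inhibitors 4 were higher (6; adjusted p = 0.071 with an estimated correlation) and of 23 immediate early genes 4 (5; adjusted p = 0.372 with an estimated correlation). Lower in SOCS1-/-IFNg-/- at 4 h were G6pc (adjusted p = 0.0395), the fatty acid oxidation regulator Ppara (-1.94 ± 0.33), and Etfbkmt (-1.78 ± 0.35). So were the lipase inhibitor G0s2 (-1.48 ± 0.33), Saa-ps (-1.45 ± 0.33), Cavin2 (-1.19 ± 0.28), Cks2 (-1.08 ± 0.28) and Ak4 (-1.02 ± 0.17). The call of Cks2 was lost in 8 and that of G6pc in 4 of 10 fits that left out a pair. The comparison was chosen after the data were seen, sets 1 array of each genotype against 10 pairs, and includes the SOCS1-/-IFNg-/- array with the lowest correlation to the others (0.979). A further probe set of Samhd1 gave -0.32.

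The duration of induction was read from the mean of the 91 induced genes. The genotype difference of this score was 0.03 untreated, 0.18 at PBS 4 h and 0.44 at PBS 12 h. After interferon-gamma it was 0.27 at 0.5 h, 0.05 at 1 h, 0.05 at 2 h, 1.36 at 4 h, 0.52 at 12 h, 0.63 at 16 h, 0.18 at 24 h and 0.02 at 48 h. Over the 8 interferon pairs the mean difference was 0.39, higher in SOCS1-/-IFNg-/- in all 8. The exact sign-flip p was 0.00781, the smallest that 8 pairs can give (adjusted p = 0.0182 over 4 tests). Of these tests, that of the 4 to 24 h pairs was chosen after the data were seen, and including it lowers this adjusted p. The differences averaged 0.21 ± 0.21 (SD, n = 3) in controls, 0.43 ± 0.62 (n = 4) early and 0.34 ± 0.29 (n = 4) late. Late minus early was -0.09 (exact permutation p = 0.83, the highest of the 4 also after adjustment) and late minus control 0.13 (exact permutation p = 0.571, adjusted p = 0.762), where the smallest possible p is 0.0286. The sign-flip test set the interferon pairs against 0 and not against the control pairs, whose differences were also above 0. It thus separated the genotypes but does not show a changed response, and the planned tests did not separate the phases. Late minus early turned to 0.17 without the 4 h pair and 0.02 without the 48 h pair.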

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

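The tests of technical explanations and the comparison of single pairs were chosen only after the results were seen; the regroupings of arrays were fixed before, except that for the 4 h pair.

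In the 4 h interferon pair 277 genes differed from the other 10 pairs, and 17 of 23 antiviral genes were higher in SOCS1-/-IFNg-/-. Scaling of the whole array is argued against, since the antiviral median of 1.75 lay at percentile 100 among 10000 lists of genes of like mean. The list is the flagged pattern itself, and its percentile does not speak to RNA quality. The SOCS1-/-IFNg-/- array of this pair had the lowest median correlation with other arrays (0.979). Its 3-prime to 5-prime Actb difference was the lowest (0.33) and that of Gapdh was 0.47. A low difference is not a mark of degraded RNA. An IFNg-/- liver taken at another time stays open: its acute phase genes correlated best with the SOCS1-/-IFNg-/- 16 h array (r across genes 0.854, against 0.779 with the 4 h array), while its clock genes correlated best with the PBS 4 h array (r = 0.947). The clock genes of the IFNg-/- 16 h array also correlated best with that array (r = 0.923), so this match does not mark a 4 h liver. The acute phase genes of the IFNg-/- 4 h array gave r = 0.834 with the PBS 4 h array. Those of the IFNg-/- 12 h array were nearest to the 16 h array (0.973, against 0.926 at 12 h). The acute phase match does not mark a time either. Less interferon acting in the IFNg-/- 4 h animal cannot be told apart from loss of SOCS1 by the acute phase genes. On the PBS 4 h arrays 19 of 26 of them stood above untreated in both genotypes (median shift 0.288). This does not separate PBS from RNA quality, as the 3-prime to 5-prime Actb difference was 0.83 and 0.66 there and 1.32 and 1.31 untreated. The median genotype difference of the acute phase genes was 0.182 in the 4 h interferon pair (17 of 26 higher) and 0.196 in the PBS 4 h pair. With 11 single pairs the regroupings are too few for a share under 0.05; the real count was 277, reached by 1 of 11, and the highest other was 1.

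Both PBS 12 h arrays carried raised interferon-inducible GTPases. Scaling of the whole array is argued against, since the GTPase median lay at percentile 100 among 10000 lists of genes of like mean on both arrays. The list is the flagged pattern itself, and its percentile does not speak to RNA quality. An exchange of labels with the 48 h interferon arrays stays open. At least 8 of 9 GTPases were higher on the PBS 12 h array than on the 24 h interferon array of the genotype, but Cxcl9 (7.76 and 8.31) lay below its 24 h values (9.38 and 10.33) and above those at 48 h (5.54 and 5.13). Among interferon arrays of the other genotype, the induced genes of the PBS 12 h arrays correlated best with the 12 h array. The r was 0.772 for IFNg-/- and 0.813 for SOCS1-/-IFNg-/-, which does not decide between the explanations. A mislabelled sample of another kind, or interferon reaching these animals, may remain and was not tested. No biological explanation was tested.

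The 18 genes that differed over all pairs could come from strain DNA around Socs1 rather than from loss of SOCS1. As a set they do not come from the window of 40 genes around Socs1, which held 1 called gene (at most 2 in any window). On average 50.3% of 8234 such windows differed as much, but an average over 40 genes can miss a change in single genes. DNA carried along beyond this window was not tested. For Clec16a the passenger explanation cannot be told apart from an effect of genotype, as it was higher in 11 of 11 pairs, which either would give. More B cells or dendritic cells stay open for the MHC class II genes. The larger of the marker medians was 0.0174 against 0.16, but members went both ways and the immunoglobulin gene Igkv6-23 was 0.59 higher. Monocyte markers were called higher over all pairs by camera, in each of 11 fits that left out a pair, but not with an estimated correlation. The monocyte gene Plac8 is among the 18. More monocytes in these livers were not tested as an explanation. Strain differences elsewhere in the genome, for example at Nnt, were not tested.

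Regroupings tested whether chance can be excluded. Over all pairs it can, since 1 of 100 sign changes, the real one, gave 18 genes and the highest other 2. With trend and robust fitting the count was 14, and without pairing 4. In controls the 4 sign changes are too few for a share under 0.05 (real count 1, reached by 1, highest other 0). Chance cannot be excluded for the early response in SOCS1-/-IFNg-/-, where 3 of 35 splits gave as many genes (1, highest other 34). Where limma called 0 genes, any split gives as many (35 of 35), so these splits decide nothing. The highest other was 1 for the early and 0 for the late response in IFNg-/-, and 76 for the late response in SOCS1-/-IFNg-/-. It was 0 for the early and 3 for the late change of the genotype difference. The splits with 34 and 76 genes set 1, 2 and 4 h, and 12, 16 and 24 h, as controls. They compared these arrays with the true controls joined by the 0.5 h or the 48 h array. They thus held most of the real contrast with its sign turned and do not measure chance. For this reason the splits of the early response in SOCS1-/-IFNg-/- do not decide on chance either.

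Among 56 tests in groups of 4 arrays, 3 had an array far from the others, where chance gives about 1 in 20, and times differ within these groups. Cxcl10 was 4.14 in IFNg-/- at 12 h, against 3.46 to 3.53 on the other late arrays. Socs1 was 6.59 in SOCS1-/-IFNg-/- at 4 h, against 6.74 to 6.77. The Gapdh 3-prime to 5-prime difference was 0.60 in SOCS1-/-IFNg-/- at 0.5 h, against 0.47 to 0.49.

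Several lists differed between the genotypes in their response by camera, and 0 of these calls held with an estimated correlation. Early, the adjusted p was 3.13e-05 for antiviral genes, 0.00768 for cell death genes and 0.0424 for MHC class I genes (all shifted up), and 0.0276 for cholesterol synthesis (down). Late and shifted down, it was 5.99e-07 for cholesterol synthesis, 5.74e-06 for P450s, 0.000278 for bile acid genes, 0.000278 for fasting metabolism and 0.000921 for fatty acid synthesis. Heat shock genes, shifted up, had 0.00103 late, with Creld2 at 1.91 and Hsph1 at 1.18. Hepatocyte markers (0.00219), Kupffer cell markers (0.0115) and complement (0.0463) shifted down late, and NK cell and monocyte markers (0.026 for both) up. In 11 fits that left out a pair, the early calls of antiviral and cell death genes were lost without the 4 h pair. Those of MHC class I genes and cholesterol synthesis were lost in 3 fits. Late, complement kept its call in 5 fits, and heat shock genes lost theirs without the untreated pair and fatty acid synthesis without the PBS 4 h pair. Kupffer cell, NK cell and monocyte markers kept theirs in 9.

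Of the 1589 probe sets with several genes or none, which the comparisons leave out, limma called 22 at 2 h, 45 at 4 h and 13 at 12 h.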

How the results depend on the processing

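The redrawn phases, the settings for the 4 h pair and the test of the 4 to 24 h pairs were chosen only after the results were seen. Since the 4 to 24 h grouping was chosen with the pair differences known, its p-values are not independent evidence. Values here are counts of called genes unless a gene is named, and the cause of a change was not tested unless fewer arrays were used. With array weights the counts were 1 at 0.5 h, 43 at 1 h, 420 at 2 h, 84 at 4 h, 51 for PBS against untreated, 4 early and 6 late in SOCS1-/-IFNg-/-, 71 over all pairs, 27 in controls and 62 for the late change of the genotype difference. With PBS arrays alone as controls (fewer arrays) they were 7 at 1 h, 86 at 2 h, 228 at 4 h, 54 at 12 h, 15 at 16 h, 9 at 24 h, 3 early and 1 late in SOCS1-/-IFNg-/-, 10 over all pairs, 2 in controls and 2 for the late change. With trend and robust fitting they were 6 at 1 h, 8 at 24 h, 0 early in SOCS1-/-IFNg-/- and 0 in controls. With all probe sets they were 22 at 1 h, 56 at 16 h, 2 at 48 h, 2 early in SOCS1-/-IFNg-/- and 2 in controls. Median centring gave 8 at 24 h and 0 at 48 h. Leaving out the genes with the lowest means gave 8 at 1 h and 2 late in SOCS1-/-IFNg-/-. A fit on that genotype alone gave 4 early, redrawn phases 0 early and 55 late, and no pairing 4 over all pairs and 0 in controls. Leaving out 1 array or pair at a time gave 0 to 1 at 0.5 h, 7 to 47 at 1 h, 86 to 287 at 2 h, 228 to 459 at 4 h, 54 to 187 at 12 h, 15 to 60 at 16 h, 7 to 22 at 24 h, 0 to 1 at 48 h and 1 to 14 for PBS. It gave 0 to 1 early and 0 late in IFNg-/-, 0 to 8 early and 0 to 66 late in SOCS1-/-IFNg-/-, 7 to 31 over all pairs, 0 to 3 in controls, 0 for the early and 0 to 2 for the late change, and 231 to 358 for the 4 h pair. The score ranged from -0.20 to 0.17 for late minus early, which reversed without the 4 h pair (0.17) and without the 48 h pair (0.02), from 0.03 to 0.23 for late minus control, from 0.28 to 0.47 over the 8 interferon pairs (exact p 0.00781 to 0.0156) and from 0.28 to 0.65 for the 4 to 24 h pairs against the other 7 (0.53 with all pairs, exact p 0.00909, adjusted p 0.0182). Reversed genes, none of them called, were Plac8 early in SOCS1-/-IFNg-/- (-0.16 with array weights, -0.19 with redrawn phases), Tap1 (-0.24 with array weights, -0.16 redrawn), Psmb8 (-0.11 redrawn) and Ifit1 (-0.092 redrawn) in the early change, and Igfbp1 (0.27 redrawn) and Hspa1b (-0.033 with PBS controls) in the late change. In controls Lpin1 (0.10) and Hspa1b (0.12) reversed with PBS controls. Leaving out a pair or array also reversed genes, with ranges of -0.66 to 0.13 for Psmb8 at 1 h, -0.19 to 0.51 for Plac8 early and -0.022 to 1.26 for Cyp7b1 late in SOCS1-/-IFNg-/-, and -0.00374 to 0.37 for Egr1 over all pairs. In controls they were -1.40 to 0.10 for Lpin1, -0.092 to 1.05 for Thrsp and -0.98 to 0.12 for Hspa1b. For the early change they were -0.16 to 0.40 for Tap1, -0.11 to 0.34 for Psmb8 and -0.092 to 1.60 for Ifit1, each lowest without the 4 h pair. For the late change they were -0.033 to 1.06 for Hspa1b and -0.018 to 0.26 for Gzma. Of 182 named calls 116 kept theirs in each fit that left out an array or pair. Of 156 list calls 25 held with an estimated correlation, and none reversed. By fry, which asks whether a list changed at all and not whether it differs from other genes, 39 of them passed. Adding an offset before taking logs was not run, since the values were already log2. Signal over background is unknown for these summaries, so genes near the floor such as Ifng give no limit.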

Other observations

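The list tests at single times given here were chosen only after the data were seen; those for phases and genotypes were not.

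Camera called monocyte markers in 8 of 17 comparisons, Kupffer cell and macrophage markers in 5 and hepatocyte markers in 3. Monocyte markers rose in 3 of 8 at 4 h (adjusted over the list alone, 5), Plac8 by 1.21, Ms4a6c by 0.46 and the Fc receptor gene Fcgr1 by 0.41 (adjusted p = 0.071 with an estimated correlation). The call of Ms4a6c was lost in 8 and that of Fcgr1 in 2 of 10 fits that left out a pair. Of 14 Kupffer cell and macrophage markers 2 rose at 4 h (2), the pore-forming gene Mpeg1 by 1.06 and the complement gene C1qb by 0.56 (adjusted p = 0.516 with an estimated correlation). The C1qb call was lost in 1 of 10 such fits. Mpeg1 rose by 1.86 at 12 h and 1.60 at 16 h, where its other probe set gave -0.03 at both. At 48 h these markers had a median of 0.24, where limma called 0 of 14 (5 adjusted over the list alone; adjusted p = 0.773 with an estimated correlation). Hepatocyte markers had a median of -0.18 at 24 h, where limma called 0 of 14 (5 lower adjusted over the list alone; adjusted p = 0.347 with an estimated correlation). Neutrophil and dendritic cell markers were called by camera early in IFNg-/- with medians of 0.04 and 0.05 (adjusted p = 0.421 with an estimated correlation for both).

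Late in SOCS1-/-IFNg-/- several metabolic lists and hepatocyte markers had negative medians and were called by camera. limma called 0 of their members over all genes (775 genes at an unadjusted p under 0.05), and 0 of these lists kept the call with an estimated correlation. Hepatocyte markers had a median of -0.19 (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.161 with an estimated correlation), with Apob at 1.28. P450s had a median of -0.22 (4 adjusted over the list alone), with Cyp2b9 at -1.03 and Cyp2b10 at -0.81 (adjusted p = 0.161 with an estimated correlation). Bile acid genes had one of -0.20, with Cyp7a1 at -1.59 (adjusted p = 0.446 with an estimated correlation), and cholesterol synthesis genes one of -0.33 (adjusted p = 0.454 with an estimated correlation). At 0.5 h acute phase proteins had a median of -0.19 in both genotypes together, where Saa2 stood at -1.27 (adjusted p = 0.602 with an estimated correlation), and the PBS 12 h arrays are among the controls. At 48 h fatty acid oxidation genes had a median of 0.12 and heat shock genes one of -0.19 (adjusted p = 0.773 with an estimated correlation for both).

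Camera called 12 of the 37 lists in none of 17 comparisons, and 9 of these 204 tests had an unadjusted p under 0.05. Their smallest adjusted p-values were 0.0565 for clock genes, 0.0644 for stellate cells, 0.0853 for erythroid cells, 0.12 for B cells, 0.136 for tryptophan and nitric oxide enzymes and 0.149 for genes that differ between the sexes. They were 0.16 for T cells, 0.163 for adipose tissue, 0.164 for the cell cycle, 0.187 for endothelial cells, 0.203 for cholangiocytes and 0.23 for pancreas.

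A fall at 4 h of more than 0.5 below both the 2 h and 12 h arrays was seen in 8 of 91 induced genes in IFNg-/- and in 0 of 91 in SOCS1-/-IFNg-/-, a count of values with no test.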
